A study of Homo sapiens with 4 samples.

How the data were processed

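The measurements are SHAPE-MaP profiles of circCAMSAP1, a circular RNA named after the gene CAMSAP1 and made by in vitro transcription. SHAPE reagents acylate the 2′-hydroxyl of flexible nucleotides, so a nucleotide held in a helix reacts less than a mobile one. Per the labels' protocols, the refolded circle was treated for 10 minutes with 100 mM NAI (2-methylnicotinic acid imidazolide) held at 37 °C, and adducts were read as mutations by SuperScript II in 6 mM Mn2+ with gene-specific primers. There were 4 libraries: 2 of folded RNA treated with NAI (native replicates 1 and 2), 1 of RNA given DMSO alone, and 1 of RNA denatured in formamide at 95 °C before NAI. No NAI concentration, time or temperature was recorded here for the denatured library, so its exposure may differ from the native one. The labels call the native libraries repeats and do not say that they are separate RNA preparations, so the spread between them may be technical. The titles name the RNA circCAMSAP1, whereas the treatment labels carry the name EPIC-1, and the name in the titles is used here.

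Per the submitters' processing notes, reads were demultiplexed with bcl2fastq 2.17.1.14. The aligner, the mutation counter, their settings and the genome build are not given in the sources used here. The deposited counts are whole numbers of mutations, reads and usable reads (effective depth) for each of 452 nucleotides, per the file headers. The deposited mutation rates are fractions, and each was checked to be the mutation count over the effective depth of the same library. The deposited reactivity is a score: recalculation gave the native minus the DMSO rate, divided by the denatured rate, with a largest gap of 7.51e-13. The deposited normalized reactivity is the same score divided by 1 constant per file, 5.29 for replicate 1 and 5.36 for replicate 2. That constant was recovered by leaving out values above the 90th percentile and averaging the next 10% of values, which gave the deposited numbers within 4.96e-07 and 5.00e-07. Columns headed as high-quality values differed from the reactivity at 0 nucleotides, so the authors' profile had no nucleotide masked. The DMSO and denatured columns are identical in both files, and each was used as 1 library.

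This processing affects the values in known ways. Dividing by the denatured rate raises the reactivity of nucleotides that are rarely mutated even when unfolded, and subtracting DMSO makes the reactivity negative at 16 nucleotides in replicate 1 and 14 in replicate 2. Because both native profiles share 1 DMSO and 1 denatured library, the counting errors of those libraries are common to both. Agreement of the replicates was therefore set beside simulations with no NAI effect. Simulations of the correlation redrew the native and DMSO counts and held the denatured rate fixed, so they leave out the counting error of the denatured library. PCR reads without molecular identifiers are not independent molecules, so intervals and count-based p-values cover counting error only.

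The median effective depth was 227848 and 297583 in the native libraries, 655226 in DMSO and 417205 in the denatured library, and the lowest at any nucleotide of any library was 88592. The widest 95% Wilson interval of a DMSO or denatured rate extended 0.0744 percentage points to either side among the 449 nucleotides kept and 0.116 among the 3 left out. The median deposited standard error of normalized reactivity was 0.0107 in replicate 1 and 0.0102 in replicate 2.

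The tests, limits, alternatives and the rule for naming nucleotides were set before the data were examined, except where a choice made later is named. Nucleotides needed an effective depth of at least 5000 in every library and a DMSO rate of at most 0.05, which left 449. C25, G180 and C245 exceeded the DMSO limit and were left out of tests, medians and folding. Numbers after a base count from 1 in the deposited numbering of the circle. Each native library was compared with DMSO and with the denatured library by 2-sided Fisher's exact tests on mutated and unmutated reads, with Benjamini-Hochberg adjustment over nucleotides and a threshold of 0.05, and a call required the same direction in both replicates. With 1 DMSO and 1 denatured library these tests compare libraries, not conditions. The replicates were compared with each other in the same way. In data simulated with known folds against DMSO on the 449 nucleotides, 46 of 67 nucleotides changed 1.2-fold were recovered (68.7%), as were 67 of 67 changed 1.5-fold and 66 of 66 changed 3-fold, and 0 of 249 unchanged nucleotides were called. These simulations, and those of unchanged libraries, carry counting error only, whereas the differences between the native replicates had an SD of 3.77 times that error.

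Reactivities of at least 0.85 in both replicates were counted as high and those below 0.4 in both as low, the customary SHAPE limits. Statistics along the RNA (the correlation of replicates, differences between bases, and areas under the receiver operating characteristic curve for unpaired over paired nucleotides) were tested by rotating one profile around the circle by every offset, a permutation test that keeps neighbouring nucleotides together. Its smallest possible p is 0.00221, and Benjamini-Hochberg values cover the 11 such tests of the family. Structures came from RNAfold 2.7.2 for circular RNA at 37 °C. The unguided fold used the sequence alone and served for tests. The guided fold added the Deigan pseudo-energy (slope 1.8, intercept -0.6) from the mean normalized reactivity, and it was described but not tested against the values that made it. A duplex was a run of nested base pairs with at most 2 unpaired nucleotides on either side at any interruption. Low-reactivity regions were runs of at least 10 nt in windows of 25 nt whose median lay below that of the whole RNA in both replicates. The native to denatured ratio was taken after subtracting DMSO from both rates, at the 440 nucleotides whose denatured rate exceeded DMSO. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and statsmodels 0.14.6.

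The rule named the 10 nucleotides of highest mean reactivity among those high in both replicates and the 10 lowest native to denatured ratios among calls with a denatured rate of at least 1.01%, the upper quartile of that library. It also named the 5 highest ratios, the 5 largest differences between replicates, the 3 longest duplexes, the 3 longest low-reactivity regions and the nucleotides within 10 nt of the point where the numbering closes. Other nucleotides named were chosen after their values were seen. Alternatives covered the depth and DMSO limits, the adjusted p threshold, a minimum fold of 1.5, scaling of rates, the normalization, the division by the denatured rate, the reactivity limits, the folding settings, the window, and each native replicate left out. Splitting the RNA by the amplicons that cover it was added after the data were seen. The position of the 452 nt in the genome was not analysed here.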

Results

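The structure of circCAMSAP1, a circular RNA of 452 nt transcribed in vitro, was probed by SHAPE-MaP to ask whether the circle holds short double-stranded regions. The series concerns a circular RNA aptamer directed at PKR, a kinase of innate immunity that is activated by double-stranded RNA. Folded RNA was treated with NAI in 2 libraries, and a DMSO library and a library of RNA denatured before NAI served as controls, with 1 library each and so no replicate error. The sequence has 111 A, 124 C, 121 G and 96 U.

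Every nucleotide was read deeply in all 4 libraries. The median read depth was 267478 in native replicate 1 (range 200259 to 481458) and 351432 in native replicate 2 (253158 to 639393). It was 711840 in DMSO (112819 to 1040029) and 459734 in the denatured library (108391 to 751186). The libraries held 3124036, 4113083, 1779762 and 2075682 mutations, in that order. Depth changed in steps that divide the circle into a part read by an amplicon from nucleotide 434 across the closure to 265, a part read by an amplicon from 217 across the closure to 45, and a part of 113 nt read by both.

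**Figure D1:**
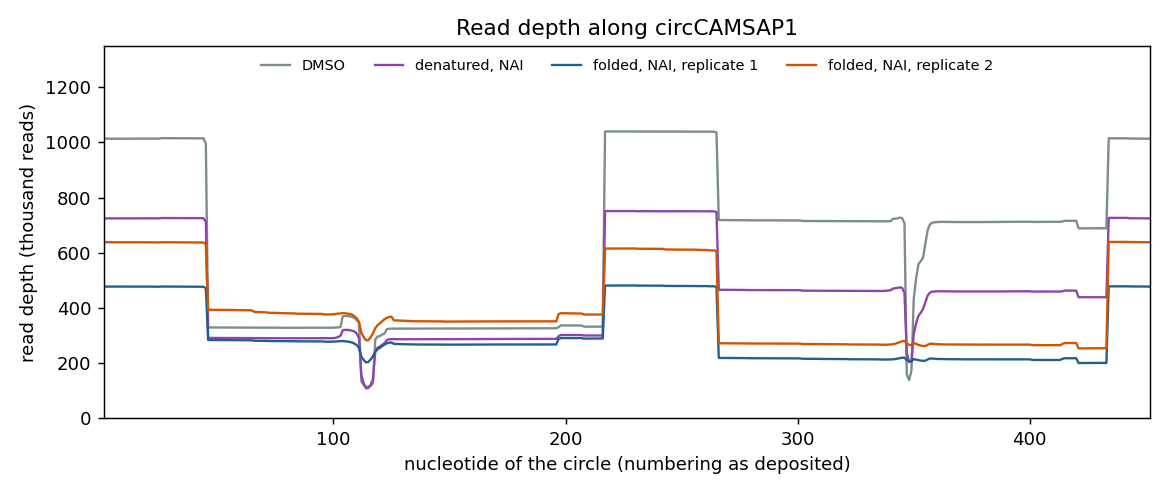
Read depth in units of 1000 reads (vertical axis) at each nucleotide of the circle (horizontal axis, deposited numbering) in the 4 libraries, 1 line each. Depth is highest where both amplicons overlap, and the DMSO and denatured lines fall sharply near nucleotides 112 to 117 and 347 to 352.

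NAI raised the mutation rate along nearly the whole circle. The median rate over nucleotides was 1.41% ± 0.0107 (SD, n = 2) in folded RNA with NAI and 0.221% with DMSO alone, a 6.37-fold difference of medians, and the median of the fold at single nucleotides was 5.40 ± 0.119 (SD, n = 2). The rate was higher than in DMSO in both replicates at 430 of 449 nucleotides (95.8%). These were 111 of 111 A, 95 of 96 U (99.0%), 117 of 120 G (97.5%) and 107 of 122 C (87.7%). At 12 nucleotides the native rate was lower than in DMSO in both replicates, 9 of them C, and 11 of the 12 were paired in the fold made without reactivities. They cluster at C93 to C95, where native rates were 0.454%, 0.694% and 0.517% against DMSO rates of 0.796%, 1.5% and 1.43%, and at C211 to U213, with 0.429%, 1.53% and 2.45% against 0.630%, 3.08% and 3.14%. The remaining 6 were C61, C142, C308, C353, G398 and G422.

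The calls rest on Fisher's exact test per nucleotide, 2-sided, at an adjusted p of 0.05, which replicate 1 passed in the higher direction at 430 nucleotides and replicate 2 at 432. Independent lists of these sizes would share 413.7, and simulations of unchanged libraries against the same DMSO counts gave at most 0 calls in both replicates (20 draws).

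**Figure D2:**
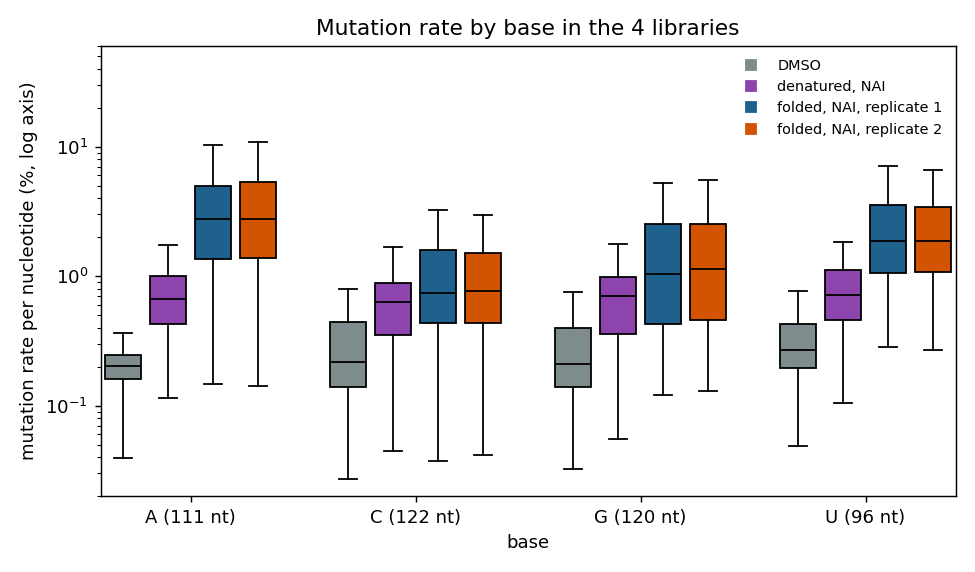
Mutation rate per nucleotide in percent (log axis) for A, C, G and U in the 4 libraries. Boxes span the quartiles with the median as a line and whiskers reach the last value within 1.5 times the interquartile range, and the medians of folded RNA with NAI, averaged over replicates, run from 0.757% for C to 2.75% for A, against 0.202% to 0.268% with DMSO.

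The native replicates gave nearly the same profile. Normalized reactivity correlated across the 449 nucleotides with a Pearson r of 0.994 and a Spearman rho of 0.996. Each had a p of 0.00221 by the 2-sided rotation (permutation) test, the smallest it can give, and an adjusted p of 0.00304 over 11 tests. Nucleotides of 1 RNA are not independent replicates. The shared DMSO library alone gave a mean r of 0.372 in 100 simulations with no NAI effect, which held the denatured rate fixed. The covariance of the unnormalized reactivities was 7.46, against 0.000243 in those simulations. The raw native rates, which share no control, correlated with an r of 0.997.

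At this depth small differences between the replicates were still detectable. Their rates differed at 189 nucleotides (42.1%, Fisher's exact test, 2-sided, adjusted p of 0.05), 124 higher in replicate 2 and 65 higher in replicate 1. At 434 nucleotides (96.7%) the rates lay within 1.2 times of each other, and the SD of the log2 ratio was 0.11. A119 stood apart, with 3.45% in replicate 1 and 5.52% in replicate 2, a 1.60-fold difference with an adjusted p of 1.22e-277 by Fisher's exact test. It lies just beyond nucleotides 112 to 117, where read depth dips in the controls, and whether this matters was not tested. A119 was the only nucleotide that differed by at least 1.5 times. The next largest were G68 (0.364% and 0.517%), C415 (0.151% and 0.200%), C260 (0.263% and 0.346%) and C386 (0.915% and 1.17%), with adjusted p-values of at most 0.000683 by the same exact test. The SD of the differences was 3.77 times the counting error, so counting error understates the spread between libraries.

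Most of the circle reacted weakly, and A carried most of the strong reactivity. Of the 449 nucleotides, 254 (56.6%) were low in both replicates, 89 (19.8%) were high in both and 96 (21.4%) lay between, while 10 (2.23%) fell in different classes in the 2 replicates. The median normalized reactivity was 0.828 ± 0.000648 for A, 0.395 ± 0.00401 for U, 0.215 ± 0.0106 for G and 0.155 ± 0.00563 for C (SD, n = 2). High reactivity was found at 52 of 111 A (46.8%), 22 of 96 U, 11 of 120 G and 4 of 122 C, the last being C161, C271, C301 and C370. Conversely, 100 of 122 C (82.0%) were low.

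The most reactive nucleotide was A145, at 3.99 ± 0.0751 (SD, n = 2), where the native rate was 16.6%, the DMSO rate 0.142% and the denatured rate 0.775%. It was followed by A258 at 2.70 ± 0.251, A341 at 2.43 ± 0.0123, A418 at 2.22 ± 0.175, and U144, the neighbour of A145, at 2.11 ± 0.0699. A32, A99, G163, A40 and A100 completed the 10, between 2.09 ± 0.0703 and 1.94 ± 0.00718. At A258 the rates were 7.15% native, 0.193% DMSO and 0.484% denatured, and at G163 they were 14.7%, 0.528% and 1.34%. In all, 8 of the 10 were A. A32 was the only 1 of the 10 paired in the unguided fold, and all 10 were unpaired in the guided fold. The values and their order depend on division by the denatured rate. Without it A145 was at 4.08, G163 at 3.52 and A99 at 3.19, A258 was at 1.72, U144 at 1.10 and A32 at 0.923, and A40 and A100, at 0.612 and 0.692, were below the limit of 0.85. A32 and A40 also lie between C25 and the end of an amplicon at 45. If reads of that amplicon are primer sequence there, they carry no adducts. They made up 39.8% and 37.6% of native but 59.1% of denatured reads, which would raise these reactivities. The reverse would hold for A258, between C245 and the end at 265 (54.0% and 55.1% against 37.7%). Primer positions are not known here, and this was not tested.

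Pooled by class, purines had a higher median reactivity than pyrimidines, 0.433 against 0.237 for the mean of the 2 replicates. The difference was 0.196 (2-sided rotation permutation test, p = 0.00221, adjusted p = 0.00304). The order did not hold base by base. G, a purine, had a median of 0.215 ± 0.0106, below U at 0.395 ± 0.00401 and above C at 0.155 ± 0.00563 (SD, n = 2). A exceeded the other bases by 0.596, 0.828 against 0.232, with the same p by the same permutation test, a contrast chosen after the data were seen. Over the 111 nucleotides read by both amplicons, a split also chosen after the data were seen, the purine difference was 0.150 and did not pass the permutation test (p = 0.292). It was 0.265 where the amplicon ending at 265 alone was read and 0.170 where the other alone was read. The part read by both holds the limits of both amplicons, where reads may be primer sequence. Whether this matters was not tested. With the customary rule that leaves out the top 2% of values and averages the next 8%, 36 nucleotides were high in both replicates in place of 89.

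**Figure D3:**
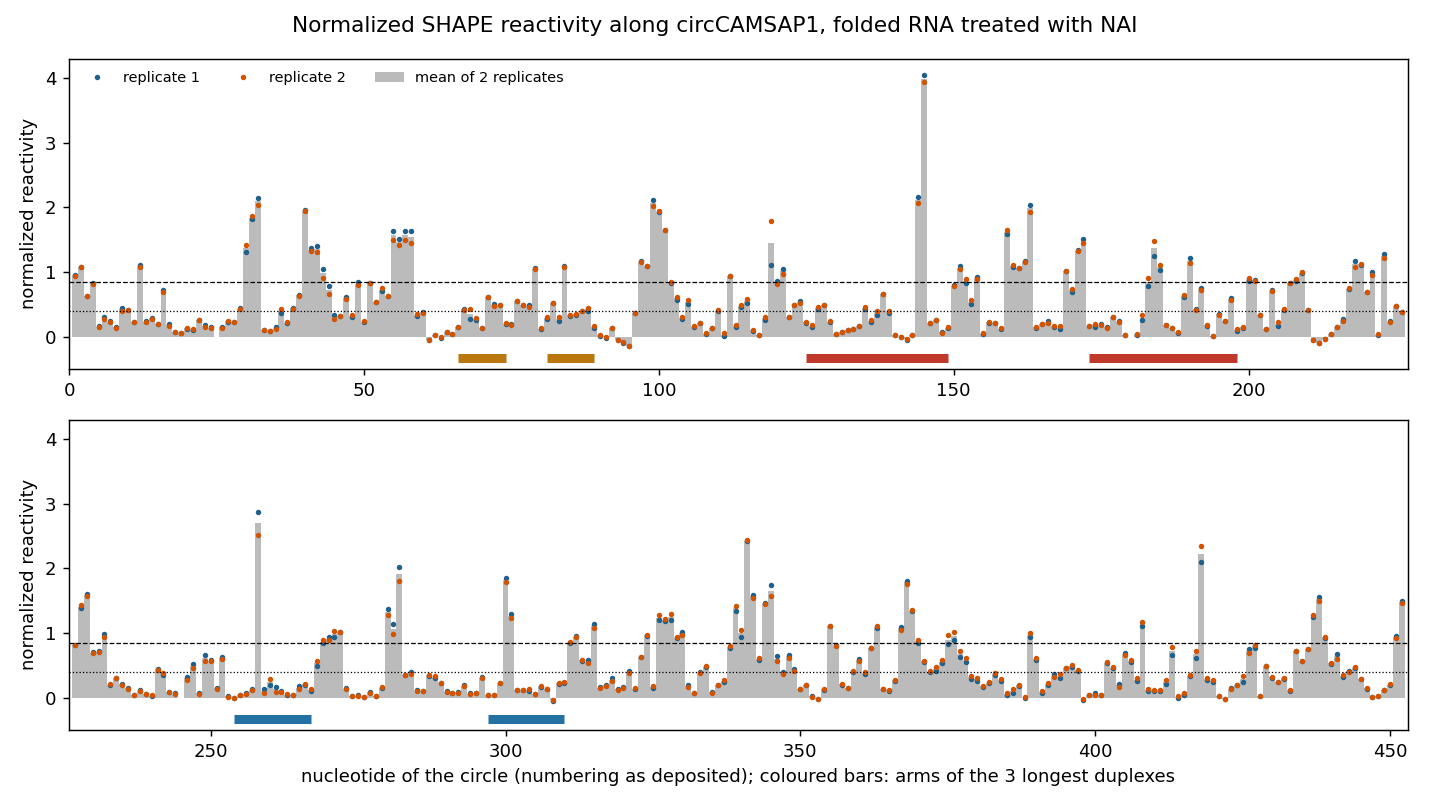
Normalized reactivity (vertical axis, no unit) of folded RNA at each nucleotide of the circle (horizontal axis, deposited numbering), with points for the 2 replicates and bars for their mean, and dotted and dashed lines at 0.4 and 0.85. The highest bar is A145 at 3.99, and coloured bars below the axis mark the arms of the 3 longest duplexes of the guided fold.

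The denatured library was the control for reactivity without structure. Its rate was higher than in DMSO at 436 of 449 nucleotides (97.1%, Fisher's exact test), but its median rate of 0.663% lay below the native one, which was 2.12-fold higher. The denatured rate was lower than that of DMSO at 5 nucleotides, C95, U205, C212, C222 and U253, and 8 did not pass the test. The denatured rates hardly differed between bases (medians of 0.663% for A, 0.628% for C, 0.708% for G and 0.721% for U), whereas the native rates ran from 0.757% for C and 1.08% for G to 1.87% for U and 2.75% for A.

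Folded RNA had a lower mutation rate than denatured RNA at 52 nucleotides (11.6%) in both replicates and a higher one at 351 (78.2%). The NAI exposure of the denatured library was not recorded, so exposure and denaturation cannot be told apart in these counts or in the ratios below. The 52 held 30 C and 18 G, and 48 of them (92.3%) were paired in the unguided fold, the others being C62, C94, C275 and C294. Of the 351, 194 (55.3%) were paired, and the difference of 37.0 percentage points had a p of 0.00221 (rotation permutation test, adjusted p = 0.00304). Native rates exceeded denatured ones at 107 of 111 A (96.4%), 86 of 96 U (89.6%), 88 of 120 G (73.3%) and 70 of 122 C (57.4%). The median ratio of native to denatured reactivity after subtraction of DMSO was 3.37 ± 0.0787 (SD, n = 2), and it was 6.76 ± 0.0656 for A, 4.17 ± 0.118 for U, 2.13 ± 0.0654 for G and 1.78 ± 0.164 for C.

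Scaling rates to equal medians (factors of 2.13 and 2.11) pushes the split of calls towards an even one by construction. It gave 209 nucleotides higher and 204 lower in both replicates, 50.6% of calls in the higher direction against 87.1% as deposited, and 82.8% of the lower and 42.1% of the higher nucleotides were paired. The replicates passed Fisher's exact test in the lower direction at 62 and 55 nucleotides (independent lists would share 7.59) and in the higher direction at 356 and 361 (286.2), and simulated unchanged libraries gave at most 0 calls in both.

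Among nucleotides with a denatured rate of at least 1.01%, the rule for the lowest native to denatured ratios named C94, C61, G398, U213, C93, G422, C63, C353, C352 and C298, with adjusted p-values of at most 8.17e-10 by Fisher's exact test. C94 had rates of 0.694% native, 1.5% DMSO and 1.66% denatured, and C61 had 2.23%, 3.31% and 3.79%. U213 had 2.45%, 3.14% and 4.01%, and C93 had 0.454%, 0.796% and 1.41%. In 8 of the 10, all but C352 and C298, the mean native rate lay below DMSO, so their ratios are negative and their order has no defined meaning. Without subtraction of DMSO the native rate was 0.323 times the denatured rate at C93, 0.417 times at C94, 0.788 times at G398 and at most 0.824 times at the others. Of the 10, 9 were paired in both folds, C94 being the exception. C352 lies in, and C353 just beyond, nucleotides 347 to 352, where read depth dips in the controls. Whether this matters was not tested. The rule for the highest ratios named U224, A101, A3, A265 and U144. At U224, A3 and A265 the denatured rate did not pass Fisher's exact test against DMSO (adjusted p = 0.329, 0.0816 and 0.665), so their ratios have no defined size or order. At A101 it was 0.219% against 0.193% (adjusted p = 0.0344 by the same exact test), which leaves its ratio poorly determined. Without subtraction of DMSO the native rates at U224, A101, A3 and A265 were 2.23, 9.68, 4.31 and 1.82 times the denatured rates. U224 and A265 also lie near the amplicon limits at 217 and 265, where reads may be primer sequence, which was not tested. At U144 the denatured rate was 0.397% against 0.230% in DMSO and the ratio after subtraction was 26.8 ± 0.653 (SD, n = 2), an error that covers the native libraries alone.

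Reactivity followed the base pairing predicted from the sequence alone. That fold had 143 base pairs, which pair 63.3% of nucleotides, and a free energy of -139.9 kcal/mol. The 166 nucleotides it leaves unpaired had a median reactivity of 0.671 ± 0.00487, and the 283 it pairs had 0.198 ± 0.000245 (SD, n = 2), with 66 of the unpaired and 23 of the paired nucleotides high in both replicates. Unpaired exceeded paired medians for each base: 1.01 against 0.410 for A, 0.641 against 0.263 for U, 0.603 against 0.157 for G and 0.288 against 0.133 for C. The area under the curve for unpaired over paired nucleotides was 0.770, and the highest of the other rotations gave 0.673 (1-sided permutation test, p = 0.00221, adjusted p = 0.00304).

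The same measure for background-subtracted rates was 0.749 in folded RNA. It was 0.567 in denatured RNA (permutation p = 0.0133, adjusted p = 0.0162) and 0.493 for the DMSO rates (permutation p = 0.573). The split by amplicon was made for normalized reactivity, at 0.770 over the whole circle. Its area under the curve was 0.810 over the part read by the amplicon ending at 265 alone. It was 0.764 over the part read by the other alone and 0.723 over the part read by both. The part read by both holds the limits of both amplicons, where reads may be primer sequence. Whether this matters was not tested.

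The reactivity-guided fold held several short duplexes and no long uninterrupted one. It had 128 base pairs covering 56.6% of nucleotides, of which 88 were shared with the unguided fold, and its longest uninterrupted helix was 8 base pairs in a structure with 17 helices of at least 4 base pairs. The 253 paired nucleotides had a median reactivity of 0.180 ± 0.00256 and the 196 unpaired ones 0.728 ± 0.00130 (SD, n = 2). The guided fold uses these reactivities, so this contrast is not a test. Among the paired nucleotides 8 were high in both replicates, A119, G280, A363, G367, U368, C370, U408 and U451.

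The longest duplex had 19 base pairs and joined nucleotides 125 to 149, GGAUGCCCUGAUGAUGGCCUACACU, with 173 to 198, GGUGGUGGCCAGUGUCAAGCGCUUCU. Its paired nucleotides had a median reactivity of 0.175 ± 0.00945 (SD, n = 2), 31 of the 37 tested were low and 0 were high. It is interrupted by 13 unpaired nucleotides, which include U144 and A145, so that its longest helix is 5 base pairs, and 18 of its 19 pairs were also in the unguided fold. The next longest had 12 base pairs and joined 254 to 267, CUGGAUCAACAAGA, with 297 to 310, UCUACGUUGACCAG. All 24 of its paired nucleotides were low, with a median of 0.117 ± 0.00233, and 10 of its pairs were in the unguided fold. Its 4 unpaired nucleotides include A258, A300 and C301, at 2.70 ± 0.251, 1.82 ± 0.0439 and 1.26 ± 0.0452. Most of the arm from 254 to 267 lies between C245 and the amplicon end at 265. Reads of that amplicon may be primer sequence there and carry no adducts. They made up 54.0% and 55.1% of native but 37.7% of denatured reads, so low reactivity in this arm may not reflect pairing alone. This was not tested.

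Another 2 duplexes had 8 base pairs each. The hairpin of 66 to 74, GUGACAGAG, with 81 to 89, CUCAGUCGC, closes a loop of 6 nt. Its median reactivity was 0.321 ± 0.0324 (SD, n = 2), 10 of 16 paired nucleotides were low, and 0 of its pairs were in the unguided fold. The duplex of 331 to 338, GCCGCCUG, with 404 to 411, CAGGUGGC, is uninterrupted. Its median was 0.231 ± 0.00831, 11 of 16 nucleotides were low, U408 was high, and all 8 pairs were in the unguided fold.

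**Figure D4:**
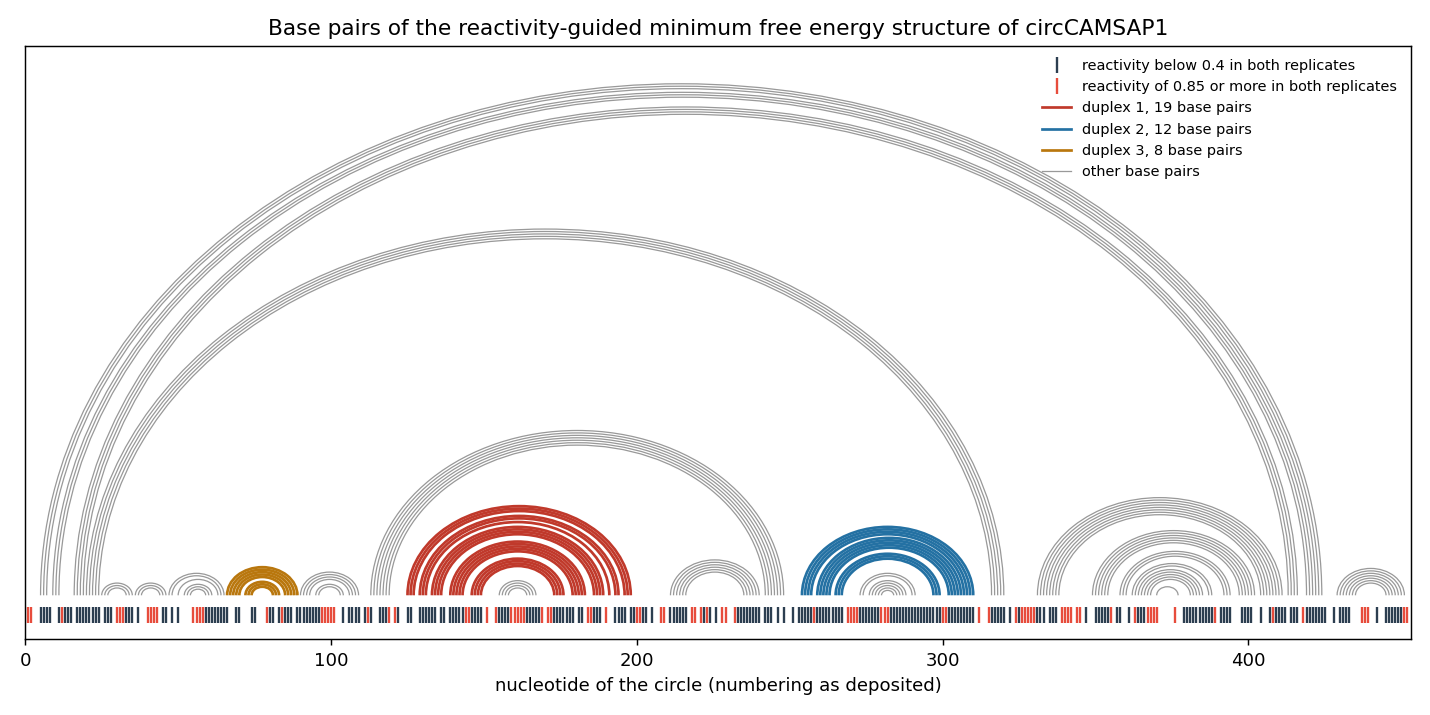
Base pairs of the guided minimum free energy fold drawn as arcs over the nucleotides of the circle (horizontal axis, deposited numbering), with the 3 longest duplexes of 19, 12 and 8 base pairs in colour and the other pairs in grey. Ticks under the arcs mark nucleotides of low (below 0.4) and high (0.85 or more) reactivity in both replicates.

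Without a folding model, 6 stretches of low reactivity covered 175 nucleotides (38.7%). Their limit is the median of the RNA itself, so many windows pass in any profile, and this share alone is no evidence of structure. The longest stretch ran from 241 to 317, 77 nt that contain the duplex of 12 base pairs, with a median reactivity of 0.161 ± 0.00915 (SD, n = 2) against 0.315 ± 0.00455 for the whole RNA. In it 55 nucleotides were low and 12 were high, among them A258, A282 at 1.91 ± 0.151 and A300. This region also spans C245 to 265, where primer sequence may lower the reactivity, as for that duplex. The others of the 3 longest were 2 to 31 (30 nt, 0.237 ± 0.000362) and 128 to 148 (21 nt, 0.211 ± 0.00315), the latter lying in an arm of the longest duplex. With a window of 51 nt only 14 of the 30 nucleotides of the region from 2 to 31 stayed in such a region, so its extent depends on the window. Nucleotides inside the 6 regions were not detectably more often paired in the unguided fold, 65.7% against 61.7% elsewhere (difference of 3.98 percentage points, permutation p = 0.296, adjusted p = 0.326). In the guided fold the shares were 64.0% and 52.0%.

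The 20 nucleotides around the closure of the numbering, 443 to 452 and 1 to 10, had a median reactivity of 0.352 ± 0.00991 (SD, n = 2), and 10 were low. U451, U452, A1 and A2, which meet at the closure, were all high, at 0.944 ± 0.0188, 1.48 ± 0.020, 0.948 ± 0.00198 and 1.08 ± 0.00444. Without division by the denatured rate U451 and A1 were at 0.445 and 0.534, and under the 2-8% normalization U451, A1 and A2 were at 0.642, 0.644 and 0.734, all below the limit of 0.85. The guided fold paired 12 of the 20 nucleotides and the unguided fold 11. These 20 nucleotides also lie near the start of an amplicon at 434. Reads of that amplicon may be primer sequence over part of them and carry no adducts. Primer positions are not known here, and this was not tested.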

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

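The splits by amplicon were the only tests of this part chosen after the results were seen. Of 99 alternatives for the main values, 11 could not move them by construction (depth limits that remove no nucleotide, and a mean of 2 replicates with 1 left out set against their SD). Of the other 88, 71 kept a count within 1.5 times, an untested value within the SD between replicates, or a tested value on its side of the threshold. A further 16 moved a count or an untested value beyond these limits, 1 no longer passed its threshold and 0 turned a direction. Of 218 for the named nucleotides, duplexes and regions, 90 could not move the value, and of the other 128, 52 kept it, 76 moved it and 0 reversed it. Some outcomes among the 88 and the 128 were still fixed by the rules. The 2-8% rule only rescales each profile and cannot move a low-reactivity region, and leaving out a replicate can only enlarge one. Either replicate alone gave the same share in such regions, so any other share counted as moved. With 1 replicate left out the native to denatured ratio ran from -2.38 to -0.780 at G398 and from -0.539 to -0.0998 at C63. Scaling rates to equal medians gave 209 nucleotides higher and 204 lower than denatured, and requiring a difference of 1.5 times left 27 lower ones. The replicates differed at 103 nucleotides at an adjusted p of 0.001 and at 1 with at least 1.5 times. The 2-8% normalization left 36 high nucleotides. Without joining across interruptions the longest duplex had 8 base pairs, while it had 19 to 24 under all other settings, and the hairpin at 66 to 89 had 0 pairs in the fold without reactivities. The share in low-reactivity regions was 40.3% without division by the denatured rate, 37.2% and 36.5% with windows of 15 and 51 nt, 31.4% with a limit of 0.3, and 42.3% (range 42.3% to 42.3%) when either replicate was left out, since 1 profile then has to meet the limit. The median native to denatured ratio was 2.17 without subtraction of DMSO. It was 2.93 where amplicon 2 (217 to 45) alone was read and 4.25 where both amplicons were read. The part read by both holds the limits of both amplicons, where reads may be primer sequence. Over that part the purine difference of 0.150 did not pass the permutation test (p = 0.292, against 0.00221 to 0.0199 under its other alternatives). Except where named, the cause was not tested. The area under the curve stayed between 0.723 and 0.810, and r between 0.991 and 0.997. Depth limits of 1000 and 20000 removed no nucleotide and so test nothing, since the lowest effective depth was 88592. What depth limits was not tested beyond counting error, which the spread between replicates exceeds. No paired analysis was possible because the DMSO and denatured groups have 1 library each and no replicate number.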

Other observations

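The tests of C25 and C245, of a kept fold, of exchanged columns and of a common factor between the replicates were chosen only after the results were seen. Within the unguided fold, median reactivity differed between types of loop. Hairpin loops had a median reactivity of 1.04 ± 0.0361 (37 nucleotides), multiloops 0.778 ± 0.0413 (18) and internal loops and bulges 0.575 ± 0.00726 (111; SD, n = 2 for each). With each base centred on its own median, hairpin loops exceeded the other loops by 0.334 (1-sided rotation permutation test, p = 0.00442). The rotated labels also fall on paired nucleotides, so this test does not compare loop types among unpaired nucleotides alone. The medians of the mean profile without centring were 1.06 and 0.596. That nucleotides are freer in hairpin loops stays an untested hypothesis. Pairs at helix ends had 0.234 ± 0.0147 (152 nucleotides) and pairs inside helices 0.163 ± 0.00251 (131; SD, n = 2). The centred difference of 0.0644 did not pass the permutation test (p = 0.170), whose rotated labels also fall on unpaired nucleotides. Whether helix ends react more stays open.

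In the native libraries the dips of read depth seen in the controls were shallow. At nucleotides 112 to 117 the lowest depth was 34.6% of the flanking median in DMSO and 37.6% in the denatured library, against 74.7% and 77.3% in the native replicates. At 347 to 352 it was 19.4% and 44.4%, against 96.4% and 99.1%. These spans, where DMSO depth fell below 80% of its running median over 41 nt, were chosen after the data were seen. Each lies in a part of the circle read by 1 amplicon alone. Whether the dips come from the layout of the reads or from the RNA was not tested.

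C25 and C245 had DMSO rates of 70.2% and 31.4%, against at most 5.08% elsewhere (at G180), and each lies 20 nt inside the end of an amplicon, at 45 and 265. A sequence difference carried by the RNA would be read alike in all libraries, but the rates spanned at least 17.3 percentage points over the libraries at each site. A candidate explanation is that reads of the amplicon ending next to the site carry a mutation beside the primer. In 6 of 6 pairs of groups the group with the larger share of reads from that amplicon had the higher rate, as at C245, where shares of 54.0%, 55.1%, 30.6% and 37.7% in native replicates 1 and 2, DMSO and denatured went with rates of 55.1%, 56.0%, 31.4% and 38.2%. At C25 the native rates of 53.8% and 52.8% exceeded the shares of 39.8% and 37.6%, which this explanation leaves open, and no biological explanation was tested. The shares of the groups at C25 and C245 ran in opposite orders. Pairs of groups at 1 site follow from 1 ordering, so the 6 pairs are not independent tests.

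The native rate exceeded the denatured one at most nucleotides, although unfolded RNA should react throughout. Exchanged DMSO and denatured columns are excluded, since the denatured rate was the higher at 436 of 449 nucleotides (Fisher's exact test). RNA that kept its native fold would give native rates at equal exposure, so a kept fold alone could not produce this pattern. The area under the curve for unpaired over paired nucleotides was lower in the denatured library than in native RNA by 0.181 (95% interval 0.131 to 0.234, 2000 bootstrap draws of blocks of 20 nt). The interval resamples nucleotides and carries no error between libraries, so it cannot tell how far a fold was kept. Modification lower by 1 common factor is also excluded as the whole cause, because the native to denatured ratio was 2.80 times higher in unpaired than in paired nucleotides (5.95 against 2.12, permutation p = 0.00221). A lower overall modification together with the loss of structure could give both values, and with 1 denatured library this stays an untested hypothesis.

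The replicates differed at 189 nucleotides, and a difference in overall modification level is excluded as the whole cause. Of common factors from 0.8 to 1.2, on the rate or on the rate above DMSO, the one that left the fewest calls in a z test of the scaled rates was 0.99, with 190 calls, 98.4% of the 193 in the same test without scaling, and these were 90 higher in replicate 1 and 100 higher in replicate 2. This test replaced scaling to equal medians, planned earlier, which tries 1 factor only and gave 208 calls. Ends of reads cannot be told apart from other sources: within 10 nt of a step in depth the median size of the log2 ratio was 1.11 times that elsewhere, with a 95% interval of 0.713 to 1.52 that spans both outcomes (permutation p = 0.385). Variation between the RNA preparations or libraries stays open and untested, and no biological explanation was tested, since both libraries have the same treatment.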
